A study of Homo sapiens with 5 samples.

How the data were processed

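Total RNA of the 5 samples was extracted with Trizol, depleted of ribosomal RNA, converted to amplified sense-strand cDNA, labelled with biotin and hybridised to 1 exon array each, per the labels' protocols. The deposited table holds log2 expression values for 22011 features (transcript clusters, which average probes over the exons of a gene) on the 5 arrays. They were made with RMA and Affymetrix Power Tools, per the submitters' processing notes, without versions. RMA corrects the background, quantile-normalizes the arrays together and summarises the probes of a feature on the log2 scale. The log base was taken from the values, which ran from 0.58 to 13.09 with nearly equal distributions (medians over all features 5.56 to 5.69). Scanner files, library files and genome build were not used here, and background detection per feature is therefore unknown. RMA can assign exactly equal values to several arrays: 6.25% to 8.97% of features had identical values in any pair of arrays, and a difference of 0 can have this origin. Array correlations were 0.989 to 0.991 within A549, 0.989 within CRL-5907 and 0.948 to 0.953 between the lines, and no pair was a repeat of the same array.

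Samples were grouped by their titles. The description of the hairpin 2 array names NEDD10 where its title and source name say NEDD9, and the title was followed. The hairpins were treated as 2 replicates of knockdown. The labels do not say whether control cells carried an empty or non-targeting construct.

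Features were named with the platform annotation: 14432 had 1 gene symbol, 2408 had several and 5171 were unnamed here. Only features with 1 symbol were used. Of these, 14404 matched an entry of the NCBI RefSeq gene table by Entrez number, and no symbol needed updating. They gave 14232 genes, of which 197 had several features and took the brightest by mean level. No coordinates are given because the array's genome build was not used here. Genes entered counts when their brightest array in the comparison lay above that array's median over named features: 7485 genes for A549, 7410 for CRL-5907, 6856 in both and 7987 between the lines.

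The log2 difference of each array from the control array of its line was computed. A gene counted as higher or lower with knockdown when both hairpins differed from control by at least 1.5-fold in the same direction, with overexpression at 1.5-fold, and between lines at 2-fold. Knockdown was also fitted with limma 3.58.1 in R 4.3.3 (lmFit and eBayes with a trend, 1 residual degree of freedom, prior 0.728) with Benjamini-Hochberg adjustment at 0.05. This test takes the spread between the hairpins as the error and assumes that the single control varies likewise. Differences between single arrays received no test. To show what a shared control gives without any effect, 100 sets of unchanged arrays were simulated, with noise resampled from the difference between the hairpins in 20 bins of level. That noise includes true differences between the hairpins, and the same noise was assumed for CRL-5907.

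The 28 gene lists (pathways, complexes, and markers of leukocytes, fibroblasts and endothelium) hold no NEDD9; like the tests, the rule for named genes and the alternatives below, they were fixed before the data were examined. The median difference over all measured members was ranked among 10000 random lists of equal size drawn from the same 20 bins of mean level. A list stood apart when outside the central 95%, for knockdown with both hairpins on the same side. By chance 1.4 of 28 lists would do so in a single comparison. These percentiles describe the arrays and are not tests across samples, and genes of a list are correlated, which the random lists and the simulation do not carry. Simulated unchanged arrays for the lists numbered 20, with 1000 random lists each.

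The steps were tested on simulated data. Of 7485 genes, 100 changed 2-fold and 100 changed 4-fold in both hairpins. The 1.5-fold rule recovered 100.0% of each, and limma recovered 33.0% of the 2-fold and 93.0% of the 4-fold genes. The simulated noise was drawn across genes of a level bin and kept no gene's own spread. These shares therefore do not give limma's power on the real arrays, where 513 of the 7485 genes had identical values with both hairpins. A list raised by 0.3 was the only one called. Genes named in the text were chosen by a fixed rule: NEDD9 and STK11, the 12 highest and 12 lowest genes of each manipulation (for knockdown by the smaller of the 2 hairpin differences), up to 8 genes each way for opposite change, the 10 highest and lowest between lines, and up to 4 leading members of each list, all among genes that passed the level filter. Genes that passed 1.5-fold in the same direction with both hairpins and overexpression were also named, which was decided after their values were seen. Alternatives were arrays centred on their medians, a further quantile normalization, the mean of a gene's features, no filter or a filter at the 75th percentile, other fold thresholds, removal of a lowess trend of the difference over level (fraction 0.3), limma without a trend, each hairpin alone, and 3 other list settings. Computation used Python 3.11.15 with numpy 2.4.6, pandas 2.3.3, statsmodels 0.14.6 and matplotlib 3.10.9.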

Results

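Gene expression was measured on 5 Affymetrix human exon arrays, each hybridised with total RNA from a human lung cancer cell line. A549 is an established lung adenocarcinoma line that carries a loss-of-function mutation of the kinase LKB1 (gene STK11) and, per the submitters, has raised NEDD9, a scaffold protein of the Cas family that sits at focal adhesions. It was profiled as a control (n = 1) and after knockdown with each of 2 different short hairpins against NEDD9 (n = 2). CRL-5907 is, per the submitters, a lung cancer line with wild-type LKB1 and a low NEDD9 level. Its LKB1 state was not checked here. This line was profiled as a control (n = 1) and with NEDD9 overexpression (n = 1). The questions the design poses are which genes change when NEDD9 is lowered in one line and raised in the other, and whether the 2 manipulations move genes in opposite directions. Each value is a normalised log2 expression level from 1 array, and array number, not read depth, limits the precision. The control arrays and the overexpression array have no replicate. Only a spread between the 2 hairpins can be given, written below as mean ± SD over the hairpins. Both hairpin differences subtract the same control array, so this SD leaves out the error of the control. The hairpins are also different constructs, and a small SD does not make a difference precise. The labels do not say whether the arrays came from separate cultures. A value below its array's median was not shown to exceed background, and a difference from such a value is read as a lower bound on its size. From the spread between the hairpins, the difference of 2 unchanged arrays had an SD of 0.197 for genes near the median level (mean log2 level 5.68) and 0.13 for the brightest genes (mean log2 level 9.84).

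NEDD9 followed the labels on all 5 arrays. In A549 its log2 level was 8.94 on the control, 8.35 with hairpin 1 and 8.52 with hairpin 2, which is 33.4% lower with hairpin 1 and 24.8% lower with hairpin 2. The mean log2 difference was -0.50 ± 0.13 (SD, n = 2), and NEDD9 stayed far above its level of 4.66 on the CRL-5907 control array. In CRL-5907 overexpression took it to 9.49, a log2 difference of 4.83 or 28.5-fold. The A549 control lay 19.4-fold above the CRL-5907 control. The CRL-5907 control value lay below that array's median of 5.69, so both folds are lower bounds. STK11 had a log2 level of 6.23 on the A549 control and 6.13 on the CRL-5907 control. Its differences of -0.13 and -0.11 with the hairpins and 0.00 with overexpression were below the SD of 2 unchanged arrays. Its values were exactly equal on the hairpin 2 array and both CRL-5907 arrays, which RMA can produce. The 0.00 therefore does not show that STK11 was unchanged. limma did not call the NEDD9 difference in A549 (adjusted p = 0.312 with Benjamini-Hochberg adjustment, 1 residual degree of freedom).

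**Figure D1:**
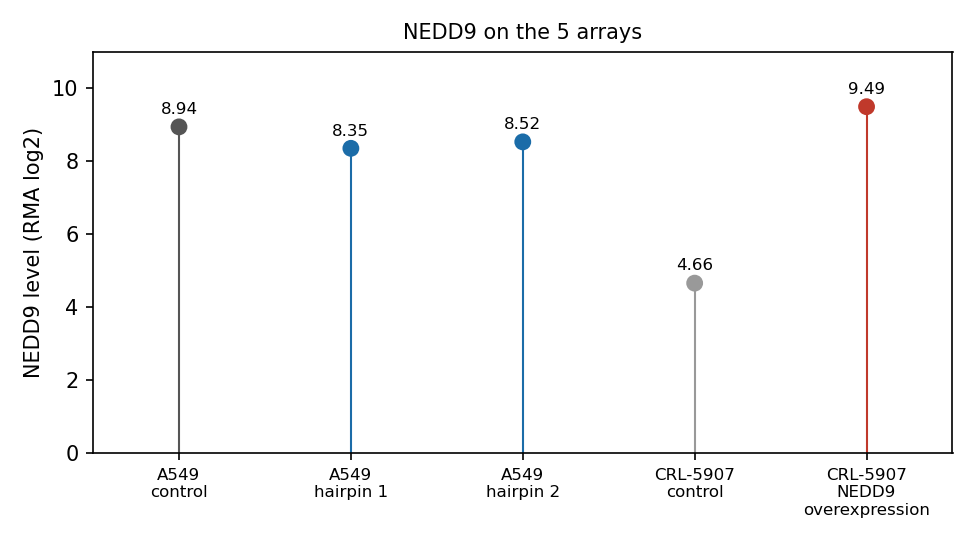
NEDD9 level (RMA log2, vertical axis) on each of the 5 arrays, 1 point per array. No error bars are drawn because each control and each construct is a single array. Both hairpin arrays (8.35 and 8.52) lie slightly below the A549 control (8.94), and the overexpression array (9.49) lies far above the CRL-5907 control (4.66).

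With NEDD9 knockdown in A549, 53 of the 7485 genes above the median level were at least 1.5-fold higher with both hairpins and 10 were at least 1.5-fold lower with both. The highest included RFX6, a transcription factor of endocrine and gut development (1.84 ± 0.37 log2, SD, n = 2), OR51E2, a G protein-coupled receptor of the olfactory family (1.43 ± 0.24), SERPINB11 (1.39 ± 0.16), OR1E1 (1.45 ± 0.11), INSL4, an insulin-family gene that LKB1-deficient lung cancers express (1.16 ± 0.05), PRR15L (1.23 ± 0.37), DLG2 (1.17 ± 0.32), ID4 (0.95 ± 0.08), USP15 (0.91 ± 0.03) and SEPTIN7 (0.88 ± 0.00). CDK1, the kinase that drives entry into mitosis, was among the 12 highest (1.08 ± 0.29). The lowest were led by PMEPA1, a feedback inhibitor of TGF-beta signalling (-0.98 ± 0.11), LOXL2, a matrix-crosslinking lysyl oxidase (-0.99 ± 0.36), WNT7B, a WNT ligand (-0.83 ± 0.09), LBH (-0.85 ± 0.19), CACNG7 (-0.83 ± 0.26), CCDC80 (-0.70 ± 0.08), SDK2 (-0.71 ± 0.10), SCD5 (-0.63 ± 0.04), PRDM12 (-0.87 ± 0.39) and SFRP1, a secreted WNT antagonist (-0.66 ± 0.11). MYCBPAP (-0.65 ± 0.10) and RGL1 (-0.65 ± 0.10) followed at differences that missed 1.5-fold with 1 hairpin each.

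These counts have to be read beside the single control array that both hairpins share. Simulated unchanged arrays against a shared control gave on average 8.8 genes higher and 9.4 lower with both hairpins (at most 16 and 17 in 100 simulations). The 53 higher genes exceeded these simulations and the 10 lower genes did not. The simulated control varied no more than a hairpin array, so a real control that deviated on its own is not covered. Genes above the median level also had a median difference of 0.10 with hairpin 1 and 0.04 with hairpin 2. Such an offset raises the higher count and reduces the lower one. After a further quantile normalization there were 40 higher and 18 lower genes, and after removal of the trend with level 44 and 16. The lower count thus lay just above or just below the simulated maximum of 17. Hairpin 1 alone gave 192 higher and 40 lower genes and hairpin 2 alone gave 101 and 36. limma called 0 of 7485 genes at an adjusted p under 0.05 with Benjamini-Hochberg adjustment (lowest adjusted p = 0.276). At an unadjusted p under 0.05 it gave 1312 genes, where 374.2 would be expected by chance. That expectation assumes a control that varies like the hairpin arrays and no offset between arrays, so the excess cannot be put down to knockdown. Of the genes counted at 1.5-fold 84.1% were higher, and this share was 69.0% after a further quantile normalization and 73.3% after removal of the trend of the difference with level. Across genes the 2 hairpins' differences correlated with r = 0.727 (rank correlation 0.735). Unchanged arrays that share a control gave r = 0.499 on average, and the covariance was 0.0354 against a simulated 0.0149. Genes are not independent replicates, so these coefficients describe the arrays only.

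Of 28 gene lists, 8 stood apart from random lists of the same size and expression level with both hairpins, 4 on the higher and 4 on the lower side. With either hairpin alone 8 lists were on the lower side. Simulated unchanged arrays gave on average 0.3 lists apart with both hairpins, and at most 1. The simulation did not carry the correlation between genes of a list, so these numbers may be too low. Medians and counts of higher and lower members cover all measured members, and the members named are those above the median level unless stated. The G2/M and mitosis list was the furthest above, with a median log2 difference of 0.38 with hairpin 1 and 0.59 with hairpin 2, higher than all 10000 random lists with each. Of its 35 measured members 32 were higher with both hairpins and 2 were lower with both. CDK1 and CCNB2, a mitotic cyclin (0.73 and 1.02), passed 1.5-fold with both, and TPX2, an activator of Aurora A (0.54 and 0.78), and BIRC5, which encodes survivin (0.53 and 0.77), passed with hairpin 2. The G1/S and replication list had medians of 0.25 and 0.32, with 26 of 30 members higher with both hairpins. None of the 17 above the median level passed 1.5-fold with both. The furthest of these were PRIM1, a DNA primase subunit (0.56 and 0.58), TYMS, thymidylate synthase (0.56 and 0.55), GINS2 (0.54 and 0.61) and MCM4, a subunit of the replicative helicase (0.51 and 0.54). Replication-dependent histones had medians of 0.21 and 0.40, with 24 of 34 higher with both. H2AC16 (0.53 and 0.80), H3C1 (0.50 and 0.64) and H1-2 (0.46 and 0.66) were furthest from control, although histone genes have near-identical copies whose probes can cross-hybridise. Ciliary and intraflagellar transport genes were higher by smaller amounts (medians 0.15 and 0.07, 17 of 25 higher with both), with OFD1 at 0.29 and 0.28 and IFT122 at 0.24 and 0.21. This list no longer stood apart when its mean, unmatched random lists or only its brighter members were used.

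On the lower side were the lists of matrix proteases, of matrix proteins, of inflammatory cytokine and NF-kB targets, and of hypoxia and glycolysis genes. Their shifts were small, and no member of these 4 lists above the median level was 1.5-fold lower with both hairpins. IL6, on the cytokine list but below that level in A549, was at -0.74 and -0.62. The protease list had medians of -0.11 and -0.08 (15 of 29 lower with both, 5 higher). MMP7, a secreted matrix metalloprotease (-0.26 and -0.27), TIMP2, a metalloprotease inhibitor (-0.28 and -0.31), and CTSB, which encodes cathepsin B (-0.13 and -0.15), were lower, and ADAM12 was higher (0.24 and 0.29). In the matrix list (medians -0.05 and -0.08, 15 of 27 lower with both) FBN2, a fibrillin, was at -1.01 and -0.23, and COL4A2, a basement membrane collagen, at -0.31 and -0.20. This list lost its place after a further quantile normalization (median of the mean difference -0.12) and among its brighter members (-0.04). In the cytokine list (medians -0.04 and -0.15, 15 of 30 lower with both) CCL5 was at -0.32 and -0.32, TNFAIP3, an NF-kB feedback inhibitor, at -0.29 and -0.32, LIF at -0.27 and -0.33 and NFKBIA, another NF-kB inhibitor, at -0.19 and -0.37. In the hypoxia and glycolysis list (medians -0.05 and -0.08, against 0.08 and 0.03 for random lists) 18 of 31 members were lower with both hairpins, among them NDRG1 (-0.52 and -0.72), ENO2, a glycolytic enolase (-0.44 and -0.46), PFKFB3, a regulator of glycolytic flux (-0.55 and -0.35), and ANGPTL4 (-0.39 and -0.34). The focal adhesion list, which holds NEDD9's own relatives and partners, was outside the central 95% of random lists with hairpin 2 (median -0.05) but not with hairpin 1 (median 0.00). It stood apart on the lower side with both under 4 alternatives: centred arrays, a further quantile normalization, the list mean and brighter members only. Among its members TGFB1I1 was at -0.33 and -0.37, TNS1 at -0.37 and -0.25, TNS3 at -0.32 and -0.24 and PARVA at 0.39 and 0.30. The integrin list did not stand apart (medians -0.02 and -0.03), with ITGA3 at -0.45 and -0.15 and ITGA6 at 0.23 and 0.31. Neither did the epithelial list (medians 0.00 and -0.02), where CLDN3 was at -0.40 and -0.40 and EPCAM at 0.62 and 0.26. CLDN3 had exactly equal values on both hairpin arrays and both CRL-5907 arrays, which RMA can produce. Its difference therefore rests on the A549 control array alone. The mesenchymal list was apart with hairpin 1 only (-0.10 against -0.02 with hairpin 2), and that difference between the hairpins was not tested.

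**Figure D2:**
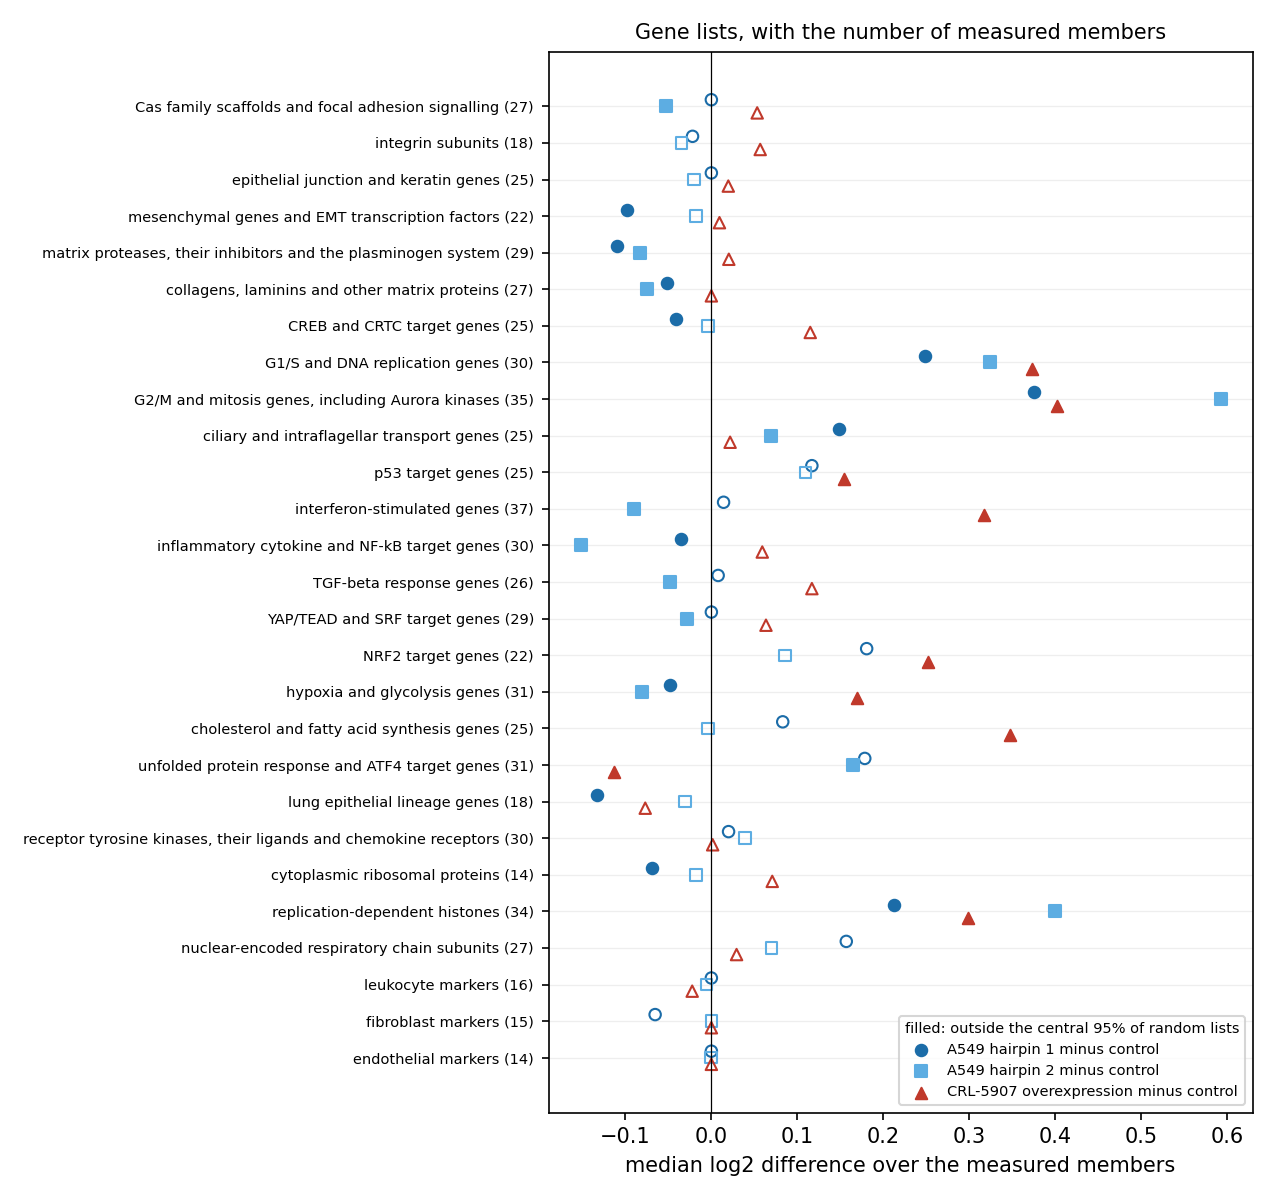
Median log2 difference from the matching control array (horizontal axis) of gene lists (1 per line, number of measured members in parentheses), with circles for A549 hairpin 1, squares for A549 hairpin 2 and triangles for CRL-5907 overexpression. Filled symbols lie outside the central 95% of 10000 random lists matched on expression. The G1/S, G2/M and histone lists are filled on the right for all 3 arrays, and the hypoxia and glycolysis list is filled on the left for the hairpins and on the right for overexpression.

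With NEDD9 overexpression in CRL-5907, 259 of the 7410 genes above the median level were at least 1.5-fold higher and 63 at least 1.5-fold lower than on the control array, where unchanged arrays gave on average 19.0 and 19.5. Apart from NEDD9, the highest of the genes above the median level were CCNA1, a cyclin (2.00 log2), FGFBP1, an FGF-binding secreted protein (1.83), PTGS2, the inducible cyclooxygenase (1.76), H3C3 (1.74), F3, tissue factor (1.72), GEM, a small GTPase (1.66), SEMA6A (1.65), IFI27, an interferon-induced gene (1.64), TGFB3 (1.63), RPL35 (1.61), H3C2 (1.59) and H3C1 (1.53). The lowest were ULBP1, a ligand of the NKG2D receptor (-1.51), TXNIP, an inhibitor of thioredoxin (-1.48), FST, follistatin (-1.28), KRTAP6-2 (-1.09), HLA-DMB (-1.07), COLCA1 (-1.03), FCGBP (-0.997), FETUB (-0.99), RPS4X (-0.97), SNTB1 (-0.94), NIBAN1 (-0.92) and SELENOP (-0.90). RPL35, RPS4X and the histones have many near-identical copies in the genome, so their values are uncertain. With 1 array in each condition the differences have no replicate check and no test was made. A further quantile normalization gave 188 higher and 111 lower genes. Of the counted genes 80.4% were higher, and this share was 62.9% after a further quantile normalization and 69.3% after removal of the trend with level.

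With overexpression 9 of the 28 lists stood apart, 8 higher and 1 lower, where unchanged arrays gave 1.25 on average and at most 5. These simulated arrays also lacked the correlation between genes of a list. Cell cycle genes were again higher, with a median of 0.40 over the G2/M list (34 of 35 members higher) and 0.37 over the G1/S list (25 of 30 higher). Only 7 of the G2/M and 14 of the G1/S members lay above the median level in CRL-5907. NUSAP1, a spindle protein (1.41), ECT2 (1.09), PLK1 (1.00), GINS1 (1.49), TYMS (1.02) and CCNE1, the G1/S cyclin (0.75), passed 1.5-fold. The histone list had a median of 0.30 over 34 members, and 7 of the 18 above the median level passed 1.5-fold. Interferon-stimulated genes had a median of 0.32, with 30 of 37 members higher, among them IFI27 (1.64), IFI6 (1.08), OAS2 (0.83) and MX1 (0.75). Cholesterol and fatty acid synthesis genes had a median of 0.35, with 22 of 25 higher, among them HMGCS1 (1.03) and IDI1 (0.87) of the mevalonate pathway, the desaturase FADS2 (0.71) and NSDHL (0.70). NRF2 targets had a median of 0.25, with HMOX1, heme oxygenase (1.16), FTL (0.90) and GCLM (0.62), while ALDH3A1 was lower (-0.78). Hypoxia and glycolysis genes had a median of 0.17 (22 of 31 higher), with PFKP (0.66), ENO2 (0.65) and NDRG1 (0.64) the furthest among members above the median level, while STC1, below it, was at 1.01. The p53 target list had a median of 0.15, with PLK2, a Polo-like kinase, at 1.38 and SESN2, a stress-response gene, at -0.37, and it no longer stood apart after removal of the trend with level (0.09) or among its brighter members. The lower list was that of the unfolded protein response and ATF4 targets (median -0.11, 22 of 31 lower), where PSAT1 (-0.42) and PHGDH (-0.40), enzymes of serine synthesis, were lower while CTH (1.20) and ATF3 (0.73) were higher.

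Several lists related to invasion did not stand apart with overexpression, although single members were higher. Some did under other settings: the CREB and CRTC list was higher after quantile normalization (0.09), after removal of the trend with level (0.13), against unmatched lists and among brighter members (0.31), the protease list among brighter members (0.20) and the cytokine list with its mean (0.16). VIM, the mesenchymal filament vimentin, was higher by 1.19 and LOXL2 by 0.71 in a mesenchymal list whose median was 0.01. The protease list had a median of 0.02, with PLAU, the urokinase plasminogen activator, at 1.00, MMP7 at 0.79 and PLAUR, the urokinase receptor, at 0.63. The cytokine list had a median of 0.06, with IL6 at 1.19, CXCL8 at 1.02, CCL2 at 0.78 and NFKBIA at 0.77. ITGB8 (0.96) was the integrin furthest from the control, and VCL, vinculin, was at 0.40 in the focal adhesion list (median 0.05). In the CREB and CRTC target list (median 0.12) PTGS2 was at 1.76, NR4A1 at 0.54 and PDE4B at -0.79. CLDN7, an epithelial claudin, was at -0.59.

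Lowering and raising NEDD9 moved few genes in opposite directions by 1.5-fold or more. The manipulations were of unequal size: NEDD9 itself was at -0.59 and -0.41 with the hairpins and at 4.83 with overexpression in the other line. A weak knockdown may leave few genes past this threshold. Of 6856 genes above the median level in both lines, LOXL2 was lower with both hairpins and higher with overexpression, and KNG1, kininogen, was higher with both hairpins (0.88 and 0.62) and lower with overexpression (-0.60). The 2 genes compare with 0.257 expected from independent lists. Genes that moved the same way with both manipulations numbered 5, against 0.80 expected, and all 5 were higher: FAM223A, RIMKLB, DTL, ANKRD42 and COX20. With hairpin 1 alone 6 genes were opposite (1.39 expected) and 11 went the same way (3.71 expected), and with hairpin 2 alone 6 (0.984 expected) and 18 (1.79 expected). Ranked by their smallest difference, the leading genes that were lower with knockdown and higher with overexpression were LOXL2 (-1.25, -0.74 and 0.71 with hairpin 1, hairpin 2 and overexpression), TNFSF15 (-0.55, -0.61 and 0.66), PMEPA1 (-1.06, -0.90 and 0.52), NDRG1 (-0.52, -0.72 and 0.64), AK4, a mitochondrial adenylate kinase (-0.47, -1.18 and 1.11), ENO2 (-0.44, -0.46 and 0.65), MMD (-0.43, -0.50 and 0.67) and HILPDA, a hypoxia-inducible lipid droplet protein (-0.42, -0.60 and 0.45). In the reverse direction ULBP1 (0.60, 0.54 and -1.51), AGR2, a secretory pathway disulfide isomerase (0.65, 0.67 and -0.53), SLC40A1, the iron exporter ferroportin (0.58, 0.52 and -0.75), CD38 (0.95, 0.81 and -0.51), TAS2R4 (0.49, 0.95 and -0.53), TM4SF5 (0.86, 0.48 and -0.53) and ZNF189 (0.82, 0.48 and -0.41) followed KNG1. Among the lists, that of hypoxia and glycolysis genes was apart on opposite sides, lower with both hairpins and higher with overexpression. Its medians with the hairpins were small (-0.05 and -0.08), and both subtract the same control array. A control that deviated in these genes is therefore not excluded, and the cause was not tested. The unfolded protein response and ATF4 list was lower with overexpression and higher with hairpin 2 (median 0.16), and with hairpin 1 (median 0.18) it reached percentile 97.2 of random lists, inside the central 95%. After a further quantile normalization, after removal of the trend with level, against unmatched lists and with the list mean it was apart on opposite sides as well. With the list mean the cytokine and TGF-beta lists, and among brighter members the protease list, were lower with both hairpins and higher with overexpression. Over all 6856 genes the mean knockdown difference and the overexpression difference correlated weakly and positively (r = 0.116, rank correlation 0.170, covariance 0.0055). The 2 comparisons share no array.

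**Figure D3:**
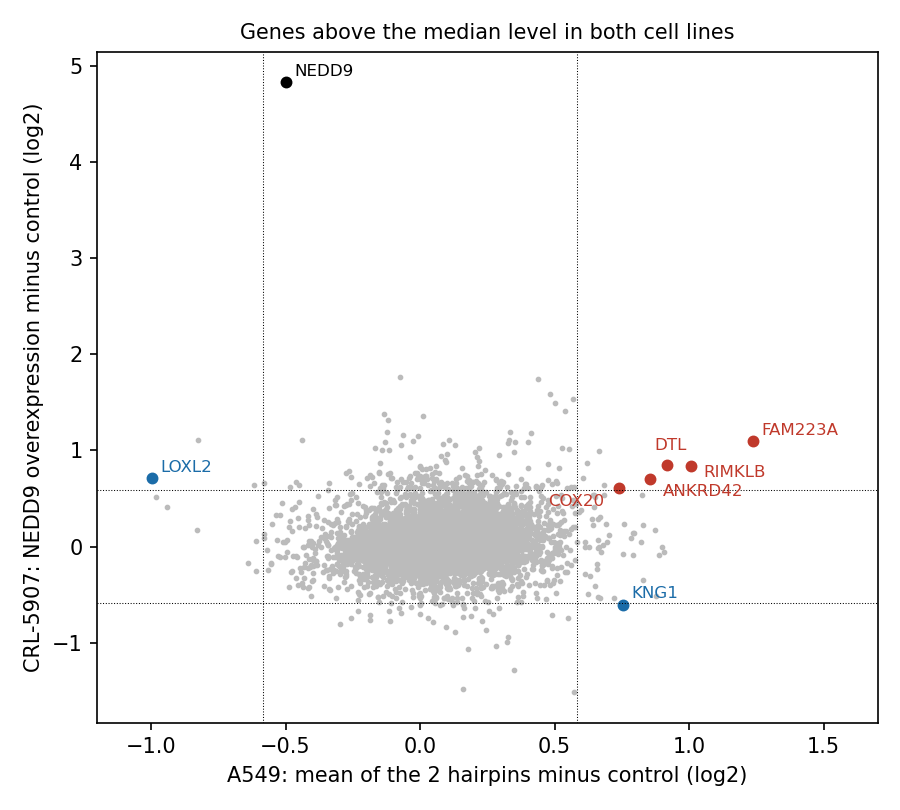
Mean log2 difference of the 2 hairpins from control in A549 (horizontal axis) against the log2 difference of NEDD9 overexpression from control in CRL-5907 (vertical axis), 1 point per gene above the median level in both lines, with NEDD9 in black. Dotted lines mark 1.5-fold. The 5 genes in red were at least 1.5-fold higher with both hairpins and with overexpression, and LOXL2 and KNG1, in blue, moved in opposite directions.

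The control arrays compared the lines themselves, which differ in LKB1 state and NEDD9 level per the submitters. At 2-fold, 801 genes were higher and 398 lower in A549 than in CRL-5907. For 791 and 393 of them all 3 A549 arrays lay on one side of both CRL-5907 arrays. This separation was largely set by choosing genes at 2-fold between the control arrays. The other arrays hold manipulated cells of the same lines and do not replicate the comparison of the controls. FN1, fibronectin (7.40 log2), DKK1, a WNT antagonist (7.08), CNTN1 (6.86), SLC27A2 (6.77), CEACAM7 (6.51) and VCAN, versican (6.27), were the highest in A549. S100A8 (-6.42), HSD17B2 (-6.12), S100A9 (-4.97), S100A12 (-4.69), TRPS1 (-4.67) and VNN1 (-4.43) were the lowest. For all of these except S100A9, and for TGFB2, TGFB1, VIM, AXL, INSIG1 and INSL4 below, the lower of the 2 values lay under its array's median, so the sizes are lower bounds and the order is approximate. Higher in A549 were the lists of TGF-beta response genes (median 0.91, 23 of 26 higher, with TGFB2 at 4.59 and TGFB1 at 2.90), G2/M genes (0.80), replication-dependent histones (0.56), hypoxia and glycolysis (0.51), YAP/TEAD and SRF targets (0.44), ciliary genes (0.40), mesenchymal genes (0.35, with VIM at 4.34 and AXL at 3.88), integrins (0.32, with ITGB5 at 1.99) and G1/S genes (0.23). The integrin list lost its place with the list mean (0.33), and the ciliary and G1/S lists among their brighter members (0.46 and 0.24). The cholesterol and fatty acid synthesis list was lower in A549 (median -0.67, 21 of 25 lower, INSIG1 at -3.77). CREB and CRTC targets did not stand apart (median 0.07), although PTGS2 (2.39) and INSL4 (2.22) were higher in A549 and CITED2 (-1.35) was lower. One line stands for each LKB1 state, so line and LKB1 state cannot be told apart.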

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

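The tests in this part were chosen after the results were seen, except the correlation without the cell cycle and histone lists. The 3 lists and 5 genes below moved the same way in every array where NEDD9 was lowered and where it was raised, so that their difference per rise in NEDD9 has opposite signs in the 2 cell lines. That difference between the lines was not tested. With overexpression the median log2 difference was 0.37 for G1/S genes, 0.40 for G2/M genes and 0.30 for histones, and with the hairpins all 3 lists were also above the central 95% of random lists. The genes were FAM223A (1.10 with overexpression, 0.95 and 1.53 with the hairpins), DTL, a ubiquitin ligase receptor that targets a replication licensing factor (0.85, 0.81 and 1.02), RIMKLB (0.84, 1.15 and 0.86), ANKRD42 (0.70, 1.01 and 0.70) and COX20 (0.61, 0.76 and 0.72).

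The higher cell cycle and histone lists could come from an A549 control array that was low in these genes. Hairpin 2 exceeded hairpin 1 by a median of 0.25 over G2/M genes, 0.22 over histones and 0.018 over G1/S genes. These values compare 1 array with 1 array and do not bear on the shift that both hairpins share, so a low control stays open for all 3 lists in A549. The overexpression arrays share no array with it. The random lists were drawn from the same bins of level, so a trend of the difference with gene level was already allowed for. Its removal was therefore only a weak further check. After it 3 of the 3 lists stayed above the central 95% with both hairpins and overexpression. An effect of NEDD9 level, of carrying a construct, or of growth state at harvest remains open and was not tested, because each condition is a single array per construct.

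The weak positive correlation of the knockdown and overexpression differences may share its origin with those lists. Without the 39 list genes among those above the median in both lines it was 0.098 ± 0.021 (SD over resampled genes) against 0.116 with them, so the lists do not carry it alone, although other cell cycle genes outside the lists remained in. After removal of the trend with level it was 0.108 ± 0.018, which argues against that trend. It fell to 0.037 among genes above the 75th percentile of level, and the cause was not tested.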

How the results depend on the processing

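No paired analysis was possible because A549 has a single control array and the sample titles name no pairing. NEDD9's differences moved by less than their spread under every alternative run, and limma called 0 genes in each of its 7 settings (lowest adjusted p between 0.112 and 0.320). Leaving out 1 hairpin cannot move a knockdown mean by more than the SD of the 2 hairpins, so for NEDD9 that alternative was fixed in advance. No list that stood apart and no gene past its fold threshold changed sign. limma could not be fitted with 1 hairpin, which leaves no residual degree of freedom. Counts depended on filter and threshold. Without a level filter 113 genes were higher and 43 lower with knockdown, 413 higher and 192 lower with overexpression, 11 opposite and 25 in the same direction. With the filter at the 75th percentile these were 20 and 3, 151 and 34, 0 and 2. At 2-fold they were 5 and 0, 52 and 6, 0 and 0. Between the lines 1.5-fold gave 1570 higher and 878 lower. Quantile normalization gave 18 lower genes with knockdown and 111 with overexpression, and removal of the level trend gave 16 lower with knockdown. With 1 hairpin alone the knockdown counts ranged from 101 to 192 higher and 36 to 40 lower; 6 to 6 genes were opposite, 11 to 18 went the same way, and the correlation with overexpression was 0.092 to 0.126. The correlation between hairpins was 0.677 without a filter and 0.712 at the 75th percentile, and that of knockdown with overexpression 0.139 and 0.037. With 1 hairpin 8 to 8 lists were lower, 4 to 5 higher. Lists lower with overexpression numbered 2 with unmatched random lists or brighter members only, and lists lower in A549 than CRL-5907 numbered 2 with the level trend removed, the list mean or brighter members only. Over single lists 582 of 635 values kept their side of the threshold, 10 lost their place (among them cilium, matrix and p53 lists) and 43 gained one (among them unfolded protein response, focal adhesion, CREB and TGF-beta lists). A knockdown list that stood apart with both hairpins could not lose its place with 1 hairpin alone. Of 1846 values of named genes 1646 moved by less than their spread and 200 by more. The 1646 include 135 knockdown values with each hairpin alone, which could not move by more. Among lists and genes short of those thresholds the sign changed in 60 list values and 8 gene values.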

Other observations

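Some lists lay outside the central 95% of random lists with 1 hairpin only, and the differences between the hairpins were not tested. Interferon-stimulated genes had a median of -0.09 with hairpin 2 and 0.01 with hairpin 1, and lung epithelial lineage genes -0.03 and -0.13. FSCN1, the actin bundler fascin, was at -0.85 with hairpin 1 and -0.25 with hairpin 2, and HGF at 0.91 and 0.13. XAF1 was the only interferon list member above the median level to pass 1.5-fold with both hairpins (0.74 and 0.66). ANKRD1, a YAP target, was higher with both hairpins (1.00 and 0.68), while its list had medians of 0.00 and -0.03. TGF-beta response genes had medians of 0.01 and -0.05, with TGFB1 at -0.40 and -0.60 and ID3 at 0.50 and 0.45. CREB and CRTC targets had medians of -0.04 and 0.00, with INSL4 the only member above the median level past 1.5-fold with both. NRF2 targets (0.18 and 0.09), p53 targets (0.12 and 0.11), respiratory chain subunits (0.16 and 0.07), receptor tyrosine kinases and ligands (0.02 and 0.04), cholesterol and fatty acid synthesis genes (0.08 and 0.00) and ribosomal proteins (-0.07 and -0.02) were not apart with both hairpins. The TGF-beta list was lower with both when its mean was used, and the YAP list with centred arrays.

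Of the markers of other cell types only 3 of 16 for leukocytes, 1 of 15 for fibroblasts and 1 of 14 for endothelium lay above the median level in A549, so medians near 0 carry little information. Leukocyte markers had medians of 0.00 and -0.01 with the hairpins and -0.02 with overexpression, fibroblast markers -0.07, 0.00 and 0.00, and endothelial markers 0.00, 0.00 and 0.00, and none of these lists stood apart. CD14, on the leukocyte list, was at -0.39 and -0.84 with the hairpins. With overexpression the lists of epithelial genes (0.02), matrix proteins (0.00), ciliary genes (0.02), TGF-beta response genes (0.12), YAP/TEAD and SRF targets (0.06), integrins (0.06), lung lineage genes (-0.08), receptor tyrosine kinases and ligands (0.00), respiratory chain subunits (0.03) and ribosomal proteins (0.07) did not stand apart. Under other settings the TGF-beta list was higher in 4 and the YAP list in 1, and the lung lineage list was lower in 2. Between the lines the protease (0.15), matrix (0.03), epithelial (0.00), interferon (-0.03), cytokine (0.01), NRF2 (0.35), p53 (-0.01) and unfolded protein response (0.04) lists did not stand apart either, although in 1 or 2 other settings the protease, matrix and NRF2 lists were higher and the epithelial, interferon and cytokine lists lower in A549. Among the 3397 (A549) and 3490 (CRL-5907) features above the median level, of 7579 with several gene symbols or none, 92 were at least 1.5-fold higher and 12 lower with both hairpins, and 198 higher and 62 lower with overexpression.

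The tests in this paragraph were chosen after the result was seen. The higher interferon-stimulated genes with overexpression may reflect delivery of a construct rather than NEDD9. The hairpin arrays, which also come from cells with a construct, had medians of 0.014 and -0.0897 for this list, but the labels say neither how constructs were delivered nor what the controls carried, and the lines differ, so this stays open. The random lists were matched on level, so removal of a trend with gene level was only a weak further check. After it the median was 0.35, above all random lists. An effect of NEDD9 itself remains among the open explanations and was not tested.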
